A study of Mus musculus with 4 samples.

How the data were processed

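Micro-C libraries of granulosa cells from punctured ovaries were prepared with the Dovetail Micro-C kit, with 2 to 3 technical replicates for each sample, per the labels' protocols. The eCG treatment before collection is given as 46 h in the sample characteristics and as 44 h in the treatment protocol, and neither could be preferred. Per the submitters' processing notes, BWA and Juicer were used with the mouse genome build mm10, and per the file headers the loop lists were written by juicer_tools 1.22.01. The version of BWA, the settings of the loop caller and the read filters are not given in the sources used here. The deposited lists, 1 per sample, are merged calls of Juicer's loop caller (HiCCUPS) in bins of 5, 10 and 25 kb, and the technical replicates of a sample are not given apart in them. Loops were therefore called in each library separately, and a deeper library can pass more loops through the caller's thresholds.

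Each deposited list gives, per the file headers, the observed contact count of a loop's pixel as a whole number, not normalized. The expected contact signal of the same pixel is given per the file headers from 4 local neighbourhoods, named bottom left, donut, horizontal and vertical. The FDR of each of these comparisons is deposited as a q-value, and all were below 0.1. The authors' lists also hold a score, the number of neighbouring pixels collapsed into the loop, which entered no comparison. Positions are in mm10 and are printed counted from 1. All loops joined 2 sites of 1 chromosome. The median observed count was 36 and 32 contacts in the PMSG libraries and 32 and 34 in the hCG libraries. A pixel with 32 contacts carries a large counting error, so single ratios are imprecise. Contacts can include PCR copies, so intervals from counts cover counting error only.

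The samples were grouped by their titles as PMSG (replicates 1 and 2) and hCG (replicates 1 and 2). Loop span is the distance between anchor midpoints. Loops of different lists matched when both anchor midpoints lay within 20 kb, and connected sets of matching loops formed 1 distinct loop. Of these sets, 3.65% were wider than 20 kb. A distinct loop was gained if it was in both hCG lists and neither PMSG list, lost if the reverse held, and common if it was in all 4 lists. Its position is that of the member in the smallest bins. Bootstrap intervals of median spans rest on 2000 draws over loops. Exact permutation tests over libraries were two-sided. Shares have Wilson 95% intervals, and comparisons of shares used Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05.

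Genes came from a table of RefSeq protein-coding genes on GRCm38.p6, the assembly of mm10, with 21631 genes placed on chromosomes 1 to 19 and X. That table gives the 2 ends of each gene and no strand, exon or transcript, so the planned transcription start sites were replaced by either annotated gene end within 2.5 kb of an anchor, and anchors could not be assigned to exons or introns. A gene end at the anchor of 1 library sufficed to place a gene at a distinct loop. A CTCF motif search at the anchors had been planned and was not run, since no genome sequence was used here. The 12 gene lists, with 259 member genes in all that were found in the table, were fixed before the data were examined, as were the grouping, tests and named genes. Named genes were list members at gained or lost loops, genes at the 10 gained and 10 lost loops that had a gene end and the highest smaller observed over expected (donut) ratio of their 2 libraries, the 5 strongest calls of loop strength in each direction, of which there were none, and 20 genes of the ovulatory response. Each list was tested for gained and for lost loops against the other genes with an end at a loop of at least 2 libraries, which gave 24 tests. The transcription factor list shares 11 genes with the LH early response list and 3 with the follicular list.

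Loop strength was tested with edgeR 4.0.16 (quasi-likelihood) in R 4.3.3 on the observed counts of pixels called in the same bin size in all 4 libraries, with the logarithm of the donut expectation as offset. DESeq2 1.42.0 with the same expectation was an alternative. On counts simulated at the 435 pixels with a dispersion of 0.01, above the fitted 0.00428, 2.21% of the calls were false. Matching was tested on simulated lists of 5754 loops moved by up to 5 kb, in which all 300 gained and 200 lost loops were recovered. Moves this small stay within the 20 kb match distance, so this recovery was fixed in advance. It does not cover loops whose anchors lie near that distance. Of 1000 random lists of 21 genes, 1.6% passed an unadjusted 0.05 in the list test. These lists were not matched on the number of loops per gene, so they do not cover lists whose genes have more loops than most. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

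The alternatives were match distances of 10 and 50 kb, overlap of both anchors, greedy matching, lists cut at an FDR of 0.01 in all 4 comparisons or at 2 times the donut expectation, each bin size alone, lists of equal length, gene ends within 0 or 10 kb, other offsets and filters for loop strength, a replicate block, and leaving out each library in turn. Further ones were added after the data had been seen, and the section on the processing names them.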

Results

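Chromatin loops were mapped by Micro-C, a form of chromosome conformation capture that cuts chromatin with micrococcal nuclease, in granulosa cells of 21-day-old mice. The mice had received 5 IU of equine chorionic gonadotropin (eCG, also called PMSG), which drives follicle growth. One group, PMSG, is labelled as 0 h after human chorionic gonadotropin (hCG), and no hCG dose is given for it. The other, hCG, was collected at 6 h after 5 IU of hCG, which stands in for the ovulatory surge of luteinizing hormone (LH). Each group had 2 libraries, with 1 list of called loops per library. The lists held 8305 and 6533 loops before hCG and 7664 and 7935 loops after it. The contact counts at the called pixels summed to 393852 and 272470 in the PMSG libraries and to 311016 and 349717 in the hCG libraries. At the 435 pixels called in all 4 libraries, the locally expected contact count relative to PMSG replicate 1 was 0.620 in PMSG replicate 2, 0.599 in hCG replicate 1 and 0.743 in hCG replicate 2. The labels call the libraries separate samples and do not say whether they came from separate mice, so the spread between them may be partly technical.

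The first question was whether the LH-like stimulus changed how many loops were called and how far they reached. The number of loops was similar, at 7419 ± 1253 (SD, n = 2) in PMSG and 7800 ± 192 (SD, n = 2) in hCG, a ratio of 1.05. Loops called after hCG spanned shorter distances. The median distance between anchors was 175 and 195 kb in the PMSG libraries and 150 and 160 kb in the hCG libraries, so the group means were 185 ± 14.1 kb and 155 ± 7.07 kb (SD, n = 2) and the difference was -30 kb. Loops longer than 200 kb made up 44.4% and 46.6% of the PMSG lists and 38.0% and 40.2% of the hCG lists, and loops longer than 1000 kb made up 3.46% and 3.89% against 2.54% and 2.79%. The Wilson 95% intervals for the share over 200 kb, which cover counting error only, were 43.4 to 45.5% and 45.4 to 47.9% for PMSG and 37.0 to 39.1% and 39.1 to 41.2% for hCG. The libraries of the 2 groups did not overlap in median span, but with 2 libraries against 2 the exact permutation test (two-sided) cannot go below p = 0.33, which was the value obtained. The difference of medians was -12.5 kb among loops called in 5 kb bins, where the groups met at 120 kb, -30 kb in 10 kb bins and -50 kb in 25 kb bins, where the groups met at 275 kb.

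**Figure D1:**
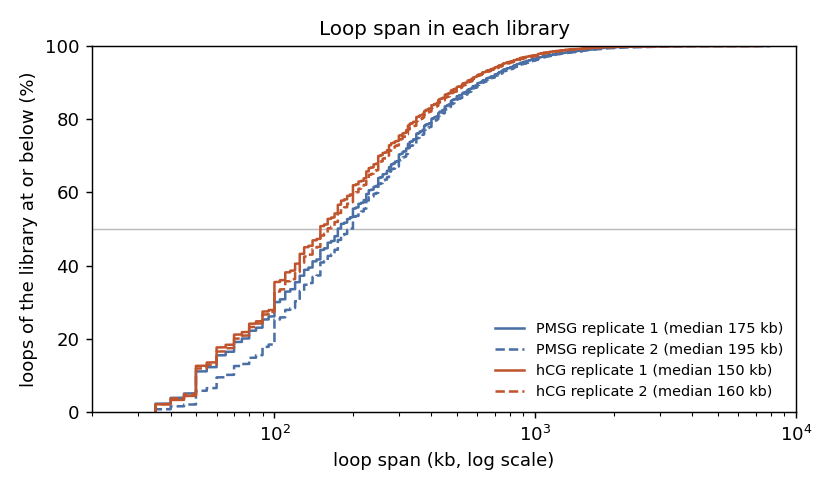
Cumulative share of each library's loops (%) against loop span (kb, log scale), with PMSG libraries in blue, hCG libraries in orange, replicate 1 as solid and replicate 2 as dashed lines. The grey line marks 50%, which the hCG libraries cross at 150 and 160 kb and the PMSG libraries at 175 and 195 kb.

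The lists were then compared with each other to ask which loops appeared or disappeared with hCG. Loops were counted as shared when both anchor midpoints lay within 20 kb. Libraries of the same group shared more loops than libraries of different groups. The Jaccard index was 0.524 for the PMSG pair and 0.534 for the hCG pair, and between 0.458 and 0.507 for the 4 mixed pairs. The within-group mean exceeded the between-group mean by 0.0491, whereas the other 2 ways of pairing the 4 libraries gave -0.0280 and -0.0211. Matching over all lists gave 12920 distinct loops, of which 3859 were called in all 4 libraries, 1697 in 3, 2200 in 2 and 5164 in 1. There were 652 loops called in both hCG libraries and in neither PMSG library, named gained here, and 491 with the opposite pattern, named lost. Together these 1143 loops outnumbered the 503 and 554 loops of the other 2 ways of pairing the libraries. Gained loops were short, with a median span of 100 kb (95% bootstrap interval 100 to 120 kb), lost loops were long, at 240 kb (220 to 270 kb), and loops common to all libraries lay between them at 175 kb (170 to 180 kb). These intervals rest on draws over loops and do not cover the spread between libraries. The classes were not compared within single bin sizes. A loop missing from a list is a pixel that did not pass the caller's thresholds, and no contact count for it was used here. When a library was left out, 1 class rested on a single list or was tested against a single list: the numbers gained were then 1404, 851, 2041 and 2026 and the numbers lost 1414, 2113, 820 and 943 without PMSG replicate 1, PMSG replicate 2, hCG replicate 1 and hCG replicate 2.

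**Figure D2:**
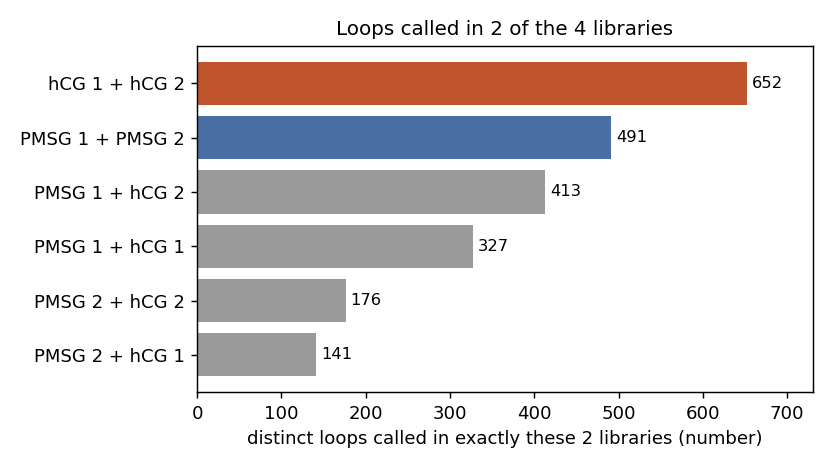
Number of distinct loops called in exactly 2 of the 4 libraries, by pair; orange marks the hCG pair (gained), blue the PMSG pair (lost) and grey the mixed pairs. The hCG pair shares 652 and the PMSG pair 491, above the mixed pairs, which share between 141 and 413.

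Among gained loops with an annotated gene end at an anchor, the strongest by the smaller observed over expected ratio of the 2 hCG libraries joined genes of several kinds. The uncharacterised gene 1700029H14Rik headed the order, with 19 and 24 contacts against 2.38 and 2.88 expected on chromosome 8. The end of Gata4, a zinc-finger transcription factor of granulosa cells, together with Neil2, met Blk on chromosome 14 (63195001 to 63200000 with 63370001 to 63375000, mm10), with 17 and 18 contacts observed against 1.75 and 2.43 expected. The other end of Gata4 met Blk in both PMSG libraries, in a lost loop of 90 kb (63270001 to 63280000 with 63360001 to 63370000) with 44 contacts against 17.4 expected in a 10 kb bin of PMSG replicate 1 and 92 against 39.5 in a 25 kb bin of PMSG replicate 2. That lost loop left its class with matching within 10 kb, with lists cut at all 4 FDR values of 0.01 and with lists of equal length. Runx2, a Runt-family transcription factor, had a loop on chromosome 17 from 44815001 to 44820000 to 44940001 to 44945000, both anchors lying inside the overlapping gene Supt3, with 20 and 23 contacts against 3.41 and 3.85 expected. Epgn, which encodes an epidermal growth factor (EGF)-like ligand, met an anchor at 91305001 to 91310000 on chromosome 5 with 19 contacts in each hCG library against 3.02 and 3.24 expected. Pappa2, a protease of insulin-like growth factor binding proteins, had 16 contacts in each hCG library against 2.07 and 2.65 expected at a loop of 240 kb. The remaining 5 of these 10 loops had ends of Flot1, Mdc1 and Tubb5 with Mrps18b and Ppp1r10, of Zfand5, of Pkhd1 with Mcm3, of Nkx2-4 and Xrn2 with Foxa2, and of Xpr1, at ratios from 5.73 to 6.92. Mcm3 and Ppp1r10 were at lost loops as well.

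The strongest lost loops with a gene end were longer. Gdap1, a mitochondrial fission gene, led with a loop of 940 kb on chromosome 1, at 14 and 16 contacts against 1.30 and 1.75 expected in the PMSG libraries. The neuropeptide Y receptor genes Npy1r and Npy5r had a loop of 710 kb with 23 and 27 contacts against 2.81 and 3.30 expected. The serotonin receptor gene Htr1a had a loop of 1470 kb, the ephrin receptor gene Epha4 of 1595 kb, Pdlim1 of 1245 kb, and Igfbp3, an insulin-like growth factor binding protein, of 1030 kb. Inhba, the activin βA subunit, had a lost loop of 305 kb on chromosome 13 (16030001 to 16035000 with 16335001 to 16340000), with 18 and 14 contacts against 2.99 and 2.22 expected. Osr1 had a lost loop of 650 kb, and Eif3f with Nlrp10 and Ccdc69 with Slc36a2 had lost loops of 115 kb each. Osr1 and Inhba were also at gained loops, of 1025 and 750 kb. Ccdc69 and Slc36a2 were joined by a gained loop of 50 kb between other anchors. The loops of Npy1r, Htr1a, Epha4, Pdlim1, Igfbp3, Osr1 and Eif3f were also called lost under each other matching rule and stricter list, without an exception. Those of Gdap1, Inhba and Ccdc69 with Slc36a2 left the class in at least 1 of these settings. Of the 10 gained loops, only those of Pkhd1 with Mcm3 and of Nkx2-4 and Xrn2 with Foxa2 kept their class in all of them. The other 8, those of Gata4, Runx2, Epgn and Pappa2 among them, did not.

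Gene lists fixed beforehand were compared with 6829 genes that had an end at a loop of at least 2 libraries, of which 759 (11.1%) lay at a gained and 499 (7.31%) at a lost loop. Transcription factors of granulosa cells were found at gained loops more often than other genes, but the call was lost against genes with as many loops. The 9 of 21 with such a loop were Cebpa, Esr2, Fosl2, Foxo1, Foxo3, Gata4, Nr5a2, Runx2 and Tead1, an odds ratio of 6.06 (Fisher's exact test, two-sided, p = 0.00021, adjusted p = 0.00505 over 24 tests of 12 lists and 2 directions). Foxo1, a forkhead factor that is active before ovulation, had a gained loop of 280 kb on chromosome 3 with 20 and 29 contacts against 4.55 and 6.00 expected. Cebpa, a CCAAT-binding factor, had gained loops on both sides, of 85 kb and 50 kb, the latter with 19 and 20 contacts against 3.84 and 3.53 expected. Nr5a2, an orphan nuclear receptor required for ovulation, had a gained loop of 60 kb with 38 and 35 contacts against 13.1 and 12.8 expected. Esr2, the estrogen receptor of granulosa cells, had a gained loop of 125 kb, and Tead1 and Foxo3 had gained loops of 225 and 780 kb. The Tead1 loop had 91 and 128 contacts against 46.0 and 57.8 expected. The loops of Foxo1 and Foxo3 kept their class in all 6 other matching rules and lists. Those of Cebpa and Nr5a2 left it when anchors had to overlap, and that of Nr5a2 also at FDR 0.01. The Esr2 loop left it with matching within 50 kb, and the Tead1 loop with lists of equal length. The 10 kb anchor of the Foxo3 loop in hCG replicate 1, at 42290001 to 42300000, did not reach Foxo3, which ends at 42276695. With a gene end required at the anchor in 2 libraries, the odds ratio of the list was 5.14 (Fisher's exact test, adjusted p = 0.0467). Loops at any gene of this list numbered 3.97 and 2.91 per 1000 loops in the PMSG libraries and 4.70 and 5.04 in the hCG libraries (3.44 ± 0.753 and 4.87 ± 0.243, SD, n = 2). At lost loops were 3 genes of the list, Fosl2, Gata4 and Klf4 (odds ratio 2.12, Fisher's exact test, adjusted p = 0.468). In a Fisher's exact test stratified by the number of loops per gene, chosen after the data had been seen, 4.13 genes were expected at gained loops (odds ratio 3.07, adjusted p = 0.252). The loops counted per gene included the gained loops themselves, which can raise the number expected. The call was also lost without hCG replicate 1 (2.90, adjusted p = 0.237) and when anchors had to overlap (3.41, adjusted p = 0.191), over a range of adjusted p from 0.00125 to 0.252 in 15 alternatives. Genes near each other and genes with several loops are not independent, so these p-values describe the lists and not the spread between mice.

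**Figure D3:**
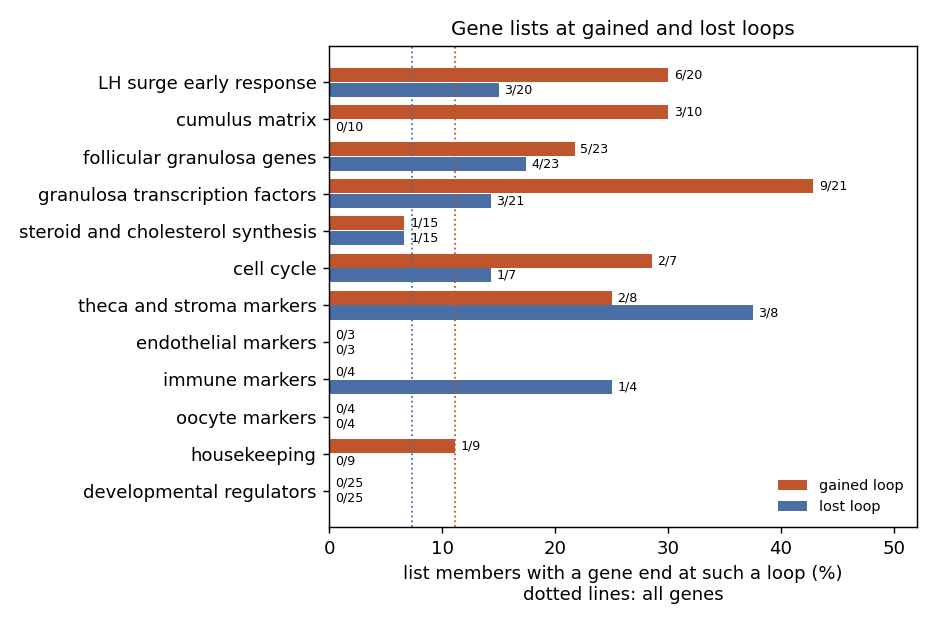
Share of each list's members with a gene end at a gained (orange) or lost (blue) loop, in % of the members at a loop of at least 2 libraries; the numbers beside the bars are members at such a loop over members counted, and the dotted lines are the shares over all genes, 11.1% and 7.31%. Granulosa transcription factors stand at 9 of 21 at gained loops, and developmental regulators at 0 of 25 in both directions.

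The other lists did not pass the test after adjustment. Of the early response to the LH surge, 6 of 20 genes were at gained loops, Atf3, Ereg, Errfi1, Fosl2, Pparg and Runx2 (odds ratio 3.45, Fisher's exact test, adjusted p = 0.146), and 3 at lost loops, Ereg, Fosl2 and Klf4 (adjusted p = 0.468); Fosl2 and Runx2 are also in the transcription factor list. Atf3, an immediate-early factor, had a gained loop of 100 kb with 108 and 152 contacts against 45.3 and 60.5 expected. Of the cumulus matrix genes, 3 of 10 were at gained loops and 0 at lost loops (Fisher's exact test, adjusted p = 0.416 and 1). These were Has2, the hyaluronan synthase of cumulus expansion, with 78 contacts against 29.1 expected in a 25 kb bin of hCG replicate 1 and 31 against 6.84 in a 10 kb bin of hCG replicate 2, Tnfaip6, which links hyaluronan to its carrier proteins, with 20 and 19 against 4.05 and 4.42, and the proteoglycan gene Vcan with 25 and 22 against 4.53 and 4.86. The Has2 loop kept its class in all 6 other matching rules and lists. The Tnfaip6 loop left it with matching within 10 kb, with overlapping anchors and at FDR 0.01, and the Vcan loop at FDR 0.01. Of genes of follicular granulosa cells, 5 of 23 were at gained loops, Esr2, Gja1, Grem1, Inhba and Nr5a2, and 4 at lost loops, Gja1, Inhba, Inhbb and Nppc (Fisher's exact test, adjusted p = 0.468 and 0.416). Nppc, the natriuretic peptide that holds the oocyte in meiotic arrest, had a lost loop of 300 kb with 21 contacts against 5.30 expected in a 5 kb bin of PMSG replicate 1 and 114 against 47.8 in a 25 kb bin of PMSG replicate 2. Of steroid and cholesterol synthesis genes, 1 of 15 was at a gained loop, Hmgcs1, and 1 at a lost loop, Akr1c18, the progesterone-inactivating 20α-hydroxysteroid dehydrogenase (Fisher's exact test, adjusted p = 1 for both). Among 7 cell cycle genes, Mcm3 and Mcm6 were at gained and Mcm3 at lost loops (Fisher's exact test, adjusted p = 0.468 and 0.707).

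Marker genes of other ovarian cell types were counted in the same way. Of 8 theca and stroma markers, Acta2, Col1a1 and Pdgfra were at lost loops (odds ratio 7.65, Fisher's exact test, adjusted p = 0.146) and Nr2f2 and Pdgfra at gained loops (adjusted p = 0.481). The lost loop of Col1a1, the collagen I chain, spanned 35 kb with 28 and 17 contacts against 7.46 and 3.06 expected. Loops at any theca or stroma marker numbered 1.69 and 1.68 per 1000 in the PMSG libraries and 1.96 and 2.14 in the hCG libraries. Of 4 immune markers, Lyz2 was at a lost loop, and of 9 housekeeping genes, Eef1a1 was at a gained loop (Fisher's exact test, adjusted p = 0.483 and 1). None of the 3 endothelial and 4 oocyte markers of the fixed lists was at a gained or lost loop (Fisher's exact test, adjusted p = 1 for all). Endothelial genes outside the list, picked from the lost loops after the results were seen, were Cd34, Calcrl, Thbd, Flt4 and Icam2. Endothelial genes at gained loops or at neither class were not counted beside them. Of all 6829 genes compared, 7.31% lay at a lost loop. Without a count of all endothelial genes, these names can neither show nor exclude an endothelial pattern. The developmental regulators of the fixed list gave 0 of 25 at gained and 0 of 25 at lost loops (Fisher's exact test, adjusted p = 0.416 and 0.483), while 19 of the 25 were at loops common to all libraries. Genes of this kind outside the list, picked after the results were seen, were at gained loops (Foxa2, Nkx2-4 and Osr1) and at lost loops (Osr1, Dmrt3, Foxf2, Tfap2a and Nkx6-2). How many such genes had no gained or lost loop was not counted. Over all genes compared, the shares were 11.1% at gained and 7.31% at lost loops.

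Genes of the ovulatory response named beforehand were then examined in each library. At the cluster of EGF-like ligands on chromosome 5, which carry the LH signal from mural granulosa cells to the cumulus, the anchors differed between the groups. Both PMSG libraries had a loop from 90.97 to 91.31 Mb and loops from its ends to anchors in Ereg, which lies at 91074617 to 91093649. In both hCG libraries, Epgn (91027517 to 91035212) was an anchor instead, with 4 loops per library and 0 in each PMSG library; one joined Epgn to Ereg with 30 and 23 contacts against 5.52 and 5.74 expected. The 3 PMSG loops counted as lost, and the outer hCG loop, at 90.95 to 91.31 Mb, as gained, although its anchor lay little more than 20 kb from that of the outer PMSG loop. With matching within 50 kb or with lists cut at all 4 FDR values of 0.01, the lost loops at Ereg and the gained loop from Epgn to 91305001 no longer belonged to their classes. One of the lost loops at Ereg also left its class when anchors had to overlap. Counted by gene ends, as for the other genes, Ereg had 0 and 2 loops in the PMSG libraries and 1 in each hCG library. The anchors of PMSG replicate 1 lay inside the gene, away from its ends. Neither Areg (91139599 to 91148432) nor Btc (91357261 to 91402994) had a gene end at a loop in any library.

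**Figure D4:**
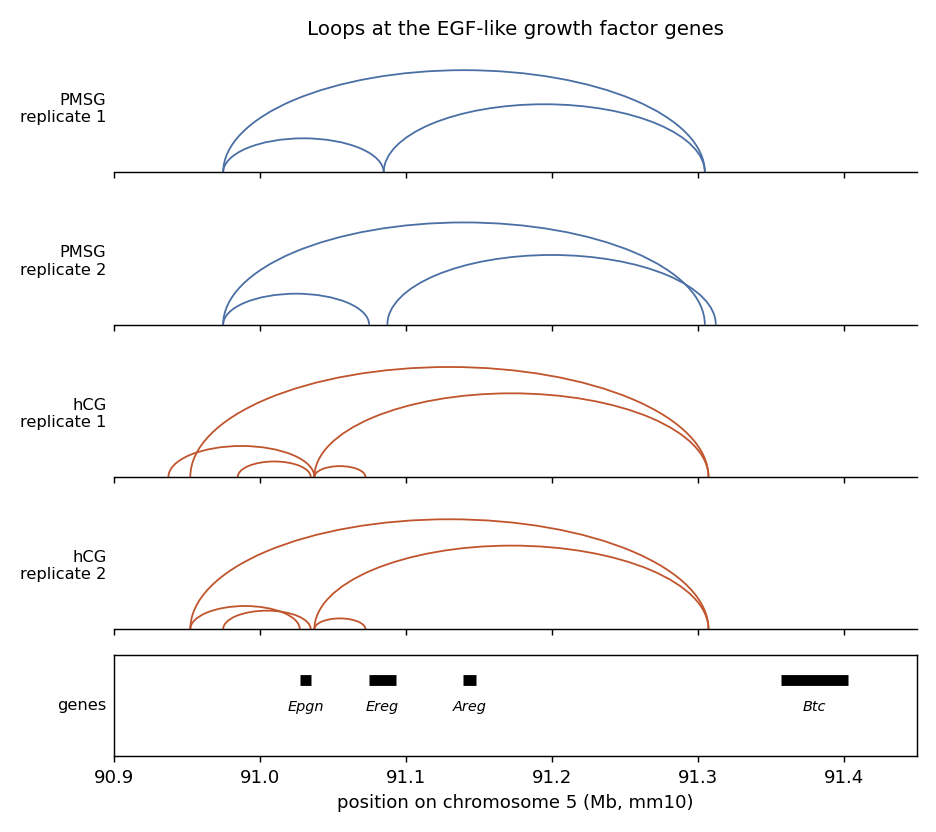
Loops called in each library (arcs between anchor midpoints, height in proportion to span) around the EGF-like ligand genes on chromosome 5 in mm10 (position in Mb), with the genes as black bars. The PMSG libraries (blue) have 3 loops each, none at Epgn, and the hCG libraries (orange) have 5 each, of which 4 have an anchor at Epgn.

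Runx2 had 0 loops in each PMSG library and 2 and 1 in the hCG libraries, Tnfaip6 likewise 0 and 0 against 2 and 1, and Has2 0 and 0 against 1 and 1. Nr5a2 had 1 and 0 against 3 and 1 loops, Gata4 3 and 1 against 3 and 2, and Esr2 2 and 1 against 1 and 3. Foxl2, the forkhead factor of granulosa identity, had 4 and 1 loops before and 4 and 2 after hCG, and Cebpb had 2 and 1 against 1 and 2. Of the steroidogenic genes, Cyp11a1, the side-chain cleavage enzyme, had 2 loops in each PMSG library and 1 in each hCG library. Both Cyp11a1 loops were called in all 4 libraries, so neither was missing after hCG. In each hCG library 1 of them had no end of the gene within 2.5 kb of its anchors. Star had 1 loop in every library, and Cyp19a1 had 0 in all. Ptgs2, the prostaglandin synthase induced by LH, had 1 loop in every library, but these were not 1 distinct loop called in all 4 libraries. The receptor genes Fshr (1 and 0 against 0 and 1) and Lhcgr (1 and 0 against 1 and 1), Inha (1 and 0 against 1 and 1), Pgr (1 and 0 against 0 and 1) and Runx1 (1 and 0 against 1 and 0) had at most 1 loop per library. Counts this small in 2 libraries per group were not tested gene by gene.

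**Figure D5:**
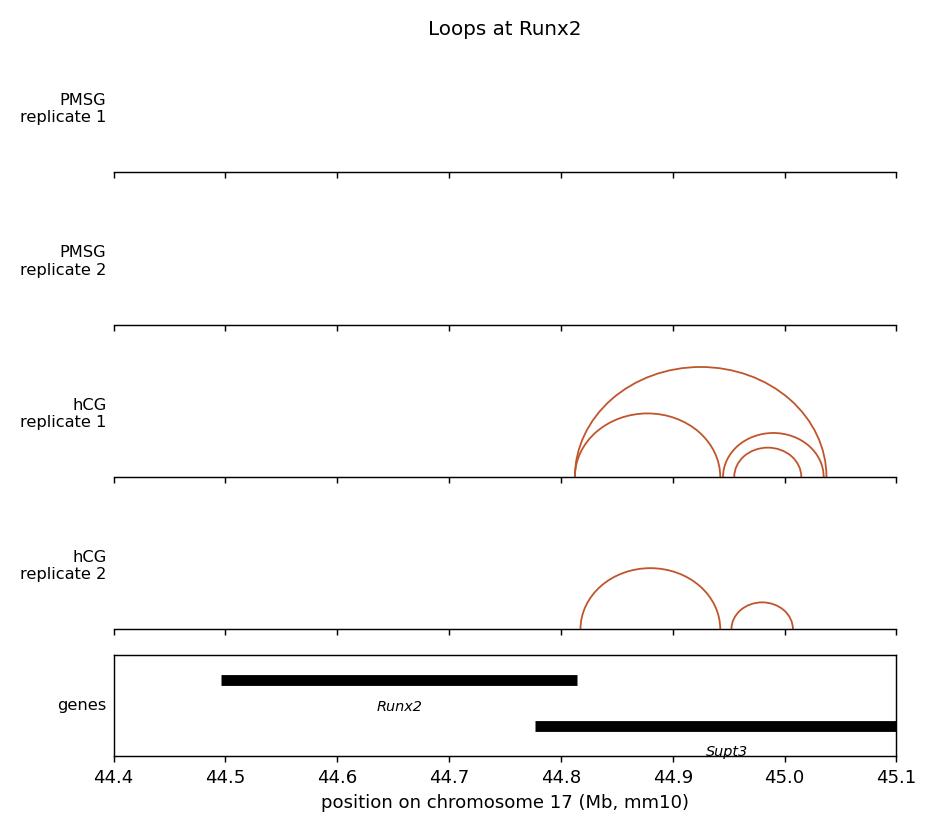
Loops called in each library (arcs between anchor midpoints, height in proportion to span) around Runx2 on chromosome 17 in mm10 (position in Mb), with Runx2 and Supt3 as black bars. No loop lies within this window in either PMSG library (blue), and the hCG libraries (orange) share a loop from the end of Runx2 at 44814797 to 44940001.

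Gained loops had a gene end at an anchor more often than lost loops. A gene end lay within 2.5 kb of at least 1 anchor in 435 of 652 gained loops (66.7%) and 294 of 491 lost loops (59.9%), with 63.7% among common loops (odds ratio 1.34, Fisher's exact test, two-sided, p = 0.0182, adjusted p = 0.0274 over 3 tests). Both anchors had one in 22.7% of gained and 15.7% of lost loops (odds ratio 1.58, Fisher's exact test, adjusted p = 0.010); Epgn and Ereg were joined in this way by a gained loop, and Gata4 and Blk by a gained and by a lost loop. Loops over 1000 kb numbered 21 among the gained and 29 among the lost, the latter including those of Htr1a and Epha4 (odds ratio 0.530, Fisher's exact test, adjusted p = 0.0398). Loops that share anchors or genes are not independent, so these p-values describe the lists and not the spread between libraries or mice. Over whole lists the share with a gene end was 57.2% and 55.2% in the PMSG libraries and 59.2% and 57.9% in the hCG libraries. The tests of both anchors and of loops over 1000 kb were not repeated under the alternatives. The first odds ratio was 2.03 without PMSG replicate 1. The call was lost without hCG replicate 1 (odds ratio 1.14, Fisher's exact test, p = 0.146), without hCG replicate 2 (1.08, p = 0.327), with matching within 10 kb (1.24, p = 0.0700), with overlapping anchors (1.16, p = 0.179) and with lists cut at all 4 FDR values of 0.01 (1.26, p = 0.0814).

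The strength of loops present throughout was compared at the 435 pixels called in all 4 libraries, where the median observed count was 32 contacts. Loops that missed the caller's thresholds in any library, or were called at differing pixels, were left out, so this test does not cover them. No loop passed the threshold in edgeR's quasi-likelihood test with the locally expected count as offset: 29 loops had an unadjusted p below 0.05, and the smallest Benjamini-Hochberg adjusted p was 0.331. DESeq2 also called 0, with 2 below an unadjusted 0.05. With pixels matched to within 1 bin, 4 of 1322 loops were called by edgeR, none of them with a gene end at an anchor. The loop with the smallest p lay on chromosome 18 from 82525001 to 82570000, with 35 and 21 contacts before and 42 and 59 after hCG, a log2 fold of 1.0 ± 0.21 (SE, n = 2 per group, edgeR, adjusted p = 0.331). Loops with an end of Tpgs2, Klf15 or Meis2, chosen after their values were seen as the first with a gene among the smallest p, had log2 folds of 0.72, 0.50 and 0.75 and an adjusted p of 0.553 each (edgeR). With 200 of the 435 loops changed in each draw, simulated changes of 1.5-fold were recovered in 35.7% of cases at these pixels, of 2-fold in 81.6% and of 3-fold in 98.9%. Changes below 2-fold would often be missed at this depth, and more often if few loops changed.

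The loops were spread over the chromosomes alike in the 4 libraries. Chromosome 2 carried the highest share, from 8.09% to 8.54%, and the X chromosome the lowest, at 2.28% and 2.45% in the PMSG libraries and 2.21% and 2.14% in the hCG libraries. The Wilson 95% intervals of the X share, from 1.98 to 2.62% and 2.10 to 2.85% against 1.90 to 2.56% and 1.85 to 2.48%, overlapped between all libraries, and the difference of the group means, -0.189 percentage points, was -0.0865 in lists cut at all 4 FDR values of 0.01.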

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

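Chosen only after the data had been seen were the equal length lists for span, the matching rules, stricter lists, whole-gene and 2-library settings for gene ends, the overlap, greedy, strict, equal length, whole-gene and 2-library settings of the gene lists, the crossed pairing, and leaving out libraries for loop numbers, span, sharing and gene ends. The ratio of loop numbers kept within its spread in all 9 settings (0.939 to 1.19 without 1 library). The span difference stayed negative in all 9, at -12.5 kb in 5 kb bins, -50 kb in 25 kb bins and -20 to -40 kb without 1 library. Sharing stayed higher within groups in all 8 (0.0364 to 0.0715 without 1 library). The difference in X share, -0.189 percentage points, was -0.0865 in lists cut at FDR 0.01. Gained and lost loops numbered 519 to 816 and 433 to 671 in the other matching rules and lists, and 851 to 2041 and 820 to 2113 without 1 library, where by construction a class rests on, or is set against, 1 list. The odds ratio for gene ends was 1.24 with matching within 10 kb, 1.16 with overlapping anchors, 1.26 at FDR 0.01 and 1.08 to 2.03 without 1 library; the cause was not tested. The transcription factor list at gained loops had 3.07 in the test matched on loops per gene, also chosen after the data had been seen, 3.41 with overlapping anchors and 2.90 to 5.14 without 1 library, and 4.16 to 7.98 otherwise. Lists without a library used genes at any loop as background. The number of lists called was 0 with matching on loops per gene and with overlapping anchors, 2 with matching within 50 kb and gene ends within 10 kb (adding theca and stroma markers, lost), 2 at FDR 0.01, with equal length lists and whole genes (adding the LH early response, gained), and 0 to 3 without 1 library, with 0 without hCG replicate 1; the cause was not tested. Median spans ran from 100 to 150 kb for gained and from 210 to 275 kb for lost loops. Of 59 named loops, 20 kept their class in all 6 other matching rules and lists, 19 in all but 1, and 20 in fewer, counting a loop absent from a shortened list as not kept.

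Loop strength gave 0 calls with the bottom-left offset, TMM, DESeq2, at least 20 contacts and the replicate block (17 at an unadjusted p below 0.05), 4 with pixels within 1 bin (1322 loops; 3 higher), and 0 to 2 without 1 library (2 without PMSG replicate 2, 1 without either hCG replicate), where the lone sample is assumed to vary like the others. The shared replicate numbers did not pair the libraries: replicate differences correlated at -0.0157 (log2 ratio to expectation) and -0.267 (log2 counts) across loops, and the crossed pairing gave 2 calls. The called pixels, chosen by these results, were at 36230001 to 39850000 (chromosome 17), 82525001 to 82570000 (18), 117700001 to 117780000 (4) and, lower, 54060001 to 54350000 (17). The start-site alternative and both CTCF alternatives were not run, for want of strand and sequence.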

Other observations

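Chosen only after the results were seen were the counts of genes with many loops, the use of anchors by the other group, the loop on chromosome 17 and the tests of depth and bin size on span and of the splits of the libraries. Some genes had a gene end at loops of 1 group alone. With at least 2 loops in both hCG libraries and 0 in both PMSG libraries there were 18 genes, against 12 with the reverse, and 9, 3, 9 and 1 for the 4 mixed pairs. After hCG these included Epgn (4 and 4 loops), Tgfbr1, a receptor of the transforming growth factor β family (3 and 3), the thymidylate kinase gene Dtymk (3 and 2), the glypican gene Gpc4 on the X chromosome (3 and 2), the chondroitin synthase gene Chsy1 (2 and 2), and Sgms1, a sphingomyelin synthase (2 and 2). Before hCG they included Bmp2, a bone morphogenetic protein (3 and 3), Txnrd3 (3 and 2), Cd34, an endothelial surface marker (2 and 2), the DM-domain gene Dmrt3 (2 and 2), Greb1l (2 and 2), and the origin recognition gene Orc4 (2 and 2). Not all of these loops met the definition of gained or lost, which needs the same loop in both libraries and no match in the other group: 4 for Epgn, 2 each for Gpc4 and Sgms1 and 1 each for Tgfbr1, Dtymk and Chsy1, and 3 for Txnrd3, 1 each for Bmp2, Cd34, Dmrt3 and Greb1l and 0 for Orc4.

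Gained and lost loops differed in how often their anchors were anchors in the other group too, which is PMSG for gained and hCG for lost loops, so the shares refer to lists of different length. The p-values here count loops and do not cover the spread between libraries. Both anchors lay within 10 kb of an anchor in both libraries of the other group for 58 of 652 gained loops (8.90%) and 75 of 491 lost loops (15.3%; odds ratio 0.542, Fisher's exact test, two-sided, p = 0.00106), and neither did for 41.7% and 38.7% (Fisher's exact test, p = 0.330). A pixel of chromosome 17 called as a loop between 36230001 and 39850000 held at least 159 contacts in each library, where 0.0526 to 0.138 were expected in each library. Whether the 2 sites lie side by side in these mice, through a strain or assembly difference, was not tested, so this pixel, which is also among the strength calls of some alternatives, is not read as a loop here.

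The gained and lost loops together numbered 1143, above the 554 of the highest other way to pair the 4 libraries. The real pairing was the only 1 of 3 to reach that number, and 3 pairings are too few for a share under 0.05. A difference in depth alone would leave the product of the 2 complementary pair counts about equal in the 3 pairings, but the real one was 5.50 times the larger of the others (95% bootstrap interval over loops 4.35 to 6.30), which argues against depth as the whole source. A response to hCG stays open, as does any unrecorded difference in handling between the groups, such as the day of collection or of library preparation.

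Loops were shorter in the hCG lists. The mix of bin sizes is argued against as the whole cause, since the difference averaged over the 3 bin sizes was -30.8 kb (95% bootstrap interval over loops -40.4 to -23.7 kb), with library means of 202 and 195 kb in PMSG and 157 and 178 kb in hCG. Depth stays open: PMSG replicate 2 and hCG replicate 1, with expected counts at shared pixels in a ratio of 1.04, differed in median span by 45 kb (35 to 50 kb, counting error only), but they are single libraries, and the PMSG libraries alone stood at 175 and 195 kb. A different fall of contacts with distance stays open too: the mean slope of the expected-count ratio over the 4 mixed pairs, 0.00611 per doubling of span (-0.00722 to 0.0209), met the bound set beforehand, but that bound was wrong, since the pairs went both ways (-0.0513, -0.0687, 0.0810 and 0.0635) and the PMSG pair alone had 0.132. An effect of hCG on loop reach cannot be told apart from these 2 accounts here.

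The transcription factor list at gained loops, 9 of 21 genes, was set against 3 technical accounts. Where lists were matched on loops, the gained loops themselves were among those counted. Among 10000 random lists matched on loops under 150 kb, as many genes at gained loops came with permutation p = 0.00050 (one-sided, mean 2.59 genes), which argues against the short span of gained loops as the whole source. More loops per gene stays open: lists matched on it gave permutation p = 0.0061 (one-sided, mean 4.07 genes, 95% of lists 1 to 7), which met the bound set beforehand, but that bound took no account of the 24 tests, and over these the odds ratio of 3.07 against genes with as many loops had an adjusted p of 0.252 (Fisher's exact test, stratified). The lower depth of PMSG replicate 2 stays open too, since the odds ratio of 4.49 (1.89 to 10.7) against PMSG replicate 1 alone decides nothing: that class holds every gained loop, so the 9 genes were fixed. The pattern is therefore not called biological here.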
